A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

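Gene expression was measured on 12 Affymetrix arrays. On the mouse platform, 7 arrays held CD11b+ cells grown from C57BL/6 bone marrow in interleukin 6 (IL-6) and granulocyte-macrophage colony-stimulating factor (GM-CSF), and 2 held CD11b+ spleen cells, depleted of Gr-1+ cells, from mice bearing EL4 lymphoma tumors. On the human platform, 3 arrays held CD14+ HLA-DR-negative or low cells from the blood of patients with head and neck squamous cell carcinoma. Per the labels, total RNA was extracted with Trizol and biotin-labelled from 100 ng by an oligo-dT-primed in vitro transcription kit. The deposited values were log2 signals per probe set, which the authors made by robust multi-array averaging (RMA) in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, makes the probe intensities of the arrays share 1 distribution and summarises each probe set. A shift shared by most genes of a sample is removed by this step, and low signals are compressed, so folds of dim genes are understated. The array medians lay between 3.10 and 3.19 on the mouse arrays and between 2.93 and 2.94 on the human arrays. The 2 platforms were handled as separately normalized, and no level was tested between them. Arrays give no read depth, and beside this compression their number limits the precision.

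Probe sets were named from the platform annotation. Of 45141 mouse probe sets, 28898 carried 1 gene symbol, 551 carried several and 15692 were unnamed here. Of 54715 human probe sets, 40875 carried 1 symbol, 864 several and 12976 were unnamed or left out here. Mouse names were compared with the GRCm38.p6 RefSeq table through Entrez identifiers, which matched for 28689 probe sets and changed 0 symbols. Only probe sets with 1 symbol were used. Where a gene had several, the one with the highest mean over the mouse arrays (or over the human arrays) stood for it, which gave 17097 mouse and 19750 human genes. The mean of all probe sets of a gene, an alternative, takes in those under the floor, while signs were compared only between probe sets above the floor on at least 2 arrays. The floor of an array was the 95th percentile of its probe sets for olfactory, vomeronasal and taste receptors, with 89 such probe sets in mouse and 162 in human. Floors lay between 2.83 and 3.13 on the mouse arrays and between 3.80 and 3.92 on the human arrays. Mouse genes above the floor on at least 2 of 9 arrays were tested, which left 11927. In human output, Y-linked genes, XIST and HLA-DRB genes were left out.

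Spleen and bone marrow-derived arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over the genes tested). Genes were called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Differences are spleen minus bone marrow-derived with the standard error (SE) of the fit, and levels are group means with the standard deviation (SD). A fold is given as "at least" where the dimmer group had no array above the floor, and was then computed from the mean floor or the gene's own signal, whichever was higher on each array. Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes, adjusted over 29 lists, and again with the correlation estimated in each list. Of 471 list members, 404 had a value and 393 were tested. Likeness to the human arrays was Spearman's rho across genes between each mouse array and the mean of the 3 human arrays, with an exact two-sided permutation test over the 36 ways to choose 2 of 9 arrays. On simulated data with 200 changed genes among 11927, in 5 runs with these group sizes, 83.4% of changes of 1.5 log2 units were called. For changes of 3 log2 units it was 97.6%, and 2.77% of calls were false. The simulated noise was independent between genes and had the bone marrow-derived SD on all 9 arrays. These rates need not hold for the real calls.

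The groups, the tests, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took the 8 largest rises and the 8 largest falls among called genes whose spleen arrays both lay outside the bone marrow-derived range. It added a fixed set around the death pathways and the sort, every called member of the 3 death pathway lists, and up to 4 called members with the smallest adjusted p of each other list with at least 3 called members. In human it took a fixed set. Genes named outside this rule are said to be so. Alternatives covered the choice of probe sets per gene, the filter and floor, a repeated quantile normalization, centring on array medians, the variance model, the size threshold, the replicate number as a block, the labels' sample numbers, and leaving out each array. With 1 spleen array left, the spread comes from the bone marrow-derived arrays alone, so a call can end from lost power without a change of the difference. Replicate numbers above 2 occur in the bone marrow-derived group only, so the block fit rests on replicates 1 and 2 of each group. Samples numbered 13, 19 and 20 in the labels are bone marrow-derived replicates 5, 6 and 7. Averaging bone marrow-derived replicates 1 with 2 and 3 with 4 was added after the data were seen. The labels give no batch or date. They do not say whether the replicates of a group came from separate animals or cultures, so p-values measure the spread between these arrays only, which may be technical.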

Results

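Myeloid suppressor cells restrain T cell responses in tumor-bearing hosts, and the series asks which pathways, death pathways in particular, act in them. RNA was profiled from 7 samples of bone marrow-derived CD11b+ cells grown in IL-6 and GM-CSF, 2 samples of splenic CD11b+ Gr-1-low cells from tumor-bearing mice and 3 samples of CD14+ HLA-DR-low blood cells of patients. CD11b (Itgam) is an integrin of myeloid cells, and Gr-1 antibodies bind the Ly6g and Ly6c proteins. Across all mouse probe sets, pairs of bone marrow-derived arrays correlated with r between 0.977 and 0.996, the spleen pair with r = 0.984, and pairs across the groups with r between 0.935 and 0.951. The median SD over genes was 0.25 log2 units in the bone marrow-derived group (n = 7), 0.19 in the spleen group (n = 2) and 0.15 in the human group (n = 3). Medians of SDs from 2 or 3 arrays run low, so these values do not rank the groups by spread. The SD of the difference between 2 arrays was 0.43 for the spleen pair and from 0.23 to 0.53 for bone marrow-derived pairs. The difference between 3-prime and 5-prime probe sets, a measure of RNA integrity, averaged 0.51 for Actb in bone marrow-derived and 0.53 in spleen arrays, and 0.36 and 0.49 for Gapdh. On the human arrays the Actb difference lay between 2.91 and 4.08 and the Gapdh difference between 0.91 and 1.24. Both are larger than the mouse averages, though the platforms use different control probe sets. Lower RNA integrity in the human samples is thus possible, and a human gene under the floor is not shown to be absent.

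**Figure D1:**
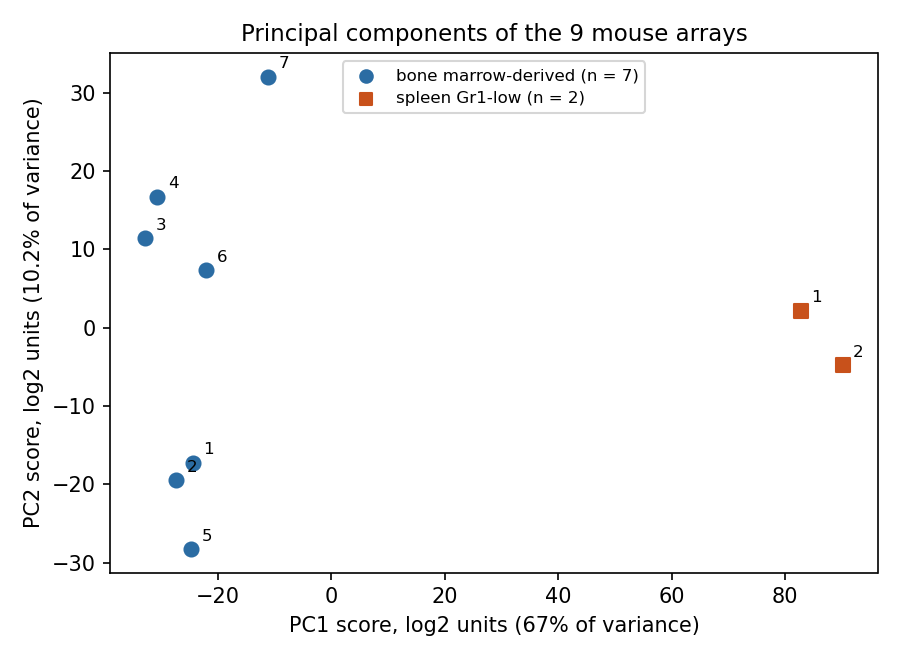
Scores of the 9 mouse arrays on the first and second principal components of the 11927 genes tested, in log2 units, with the replicate number beside each point (circles, bone marrow-derived; squares, spleen). The first component, with 67% of the variance, puts the spleen arrays at 82.8 and 90.1 and all bone marrow-derived arrays below 0, and the second, with 10.2%, spreads the bone marrow-derived arrays.

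The first comparison asked how suppressor cells taken from the spleen differ from those grown in culture. The largest rise in spleen was Jchain, the joining chain of secreted antibodies, at 12.34 ± 0.23 (SD, n = 2) in spleen and 2.38 ± 0.24 (n = 7) in bone marrow-derived cells. This is a log2 difference of 9.96 ± 0.21 (SE), or at least 674.5-fold, since no bone marrow-derived array lay above the floor. The other large rises, in no order, were the hemoglobin genes Hba-a1 (9.33 ± 0.41) and Hbb-b2 (7.85 ± 0.27), the immunoglobulin light chain genes Igk-V21 (9.02 ± 0.18, at least 373-fold), Iglv1 (7.81 ± 0.68) and a second kappa variable segment (7.57 ± 0.19, at least 120-fold), and the macrophage-secreted proteins Cd5l (7.36 ± 0.51) and Fcna (7.28 ± 0.29). Immunoglobulin probe sets can bind transcripts of related segments, so single segments are uncertain. With the mean of all probe sets, which takes in dim ones, Hbb-b2 rose by 2.80 and Igk-V21 by 4.21, and without probe sets that can bind several genes Igk-V21 rose by 2.24. The large falls, likewise in no order, were Ccn3 (-8.74 ± 0.41, at least 208-fold lower, with no spleen array above the floor), the cysteine protease inhibitor Stfa3 (-7.75 ± 0.24), eosinophil peroxidase Epx (-7.48 ± 0.19, at least 136-fold lower), the elastase Mmp12 (-7.11 ± 0.26), Gpnmb (-6.81 ± 0.29), Serpinb2 (-6.74 ± 0.29), Plet1 (-6.52 ± 0.55) and the chemokine Ccl8 (-6.45 ± 0.24). One of the 3 Plet1 probe sets differed in sign, and their mean fell by 3.80 (Plet1). All 16 of these had an adjusted p of at most 4.37e-06.

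In all, 965 genes were higher and 968 lower in spleen among the 11927 tested, which is 16.2%. Of the called genes, 98 that were higher had no bone marrow-derived array above the floor and 60 that were lower had no spleen array above it. The median difference over all genes tested was -0.05. Itgam itself, the marker used in both sorts, was at 8.81 ± 0.36 (n = 7) in bone marrow-derived cells and 7.01 ± 0.01 (n = 2) in spleen, a log2 difference of -1.80 ± 0.24 (adjusted p = 1.4e-04). Ly6g and Ly6c2 were unnamed on the platform as annotated here, so the Gr-1 depletion was not checked. The tumor-bearing host, the tissue, the culture and the handling all differ between the 2 groups and cannot be separated.

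For the death pathways, the genes the series is about, Cflar and Mcl1 were expressed on every mouse array and neither was called between the groups. Cflar, which encodes the caspase-8 inhibitor c-FLIP, was at 7.26 ± 0.70 (n = 7) in bone marrow-derived and 7.35 ± 0.03 (n = 2) in spleen cells, a difference of 0.09 ± 0.42 (adjusted p = 0.89). Its bone marrow-derived values lay between 6.61 and 7.17 on 6 arrays and at 8.78 in replicate 5, without which the difference was 0.35 (adjusted p = 0.17), while it was -0.01 without replicate 7. Of the 5 Cflar probe sets, 2 had the sign of the one used. The mean of all 5 gave -0.31 (adjusted p = 0.32), so its direction is not settled. Mcl1, an anti-apoptotic BCL-2 family gene, was at 10.84 ± 0.27 and 11.66 ± 0.01, a difference of 0.82 ± 0.18 (adjusted p = 0.0044) that stayed under the size threshold. Casp8 differed by -0.51 ± 0.19 (adjusted p = 0.066) and the necroptosis kinase gene Ripk3 by -0.83 ± 0.17 (adjusted p = 0.0028), likewise under the size threshold, while without spleen replicate 2 Ripk3 was called at -1.11. The BH3-only gene Bcl2l11 differed by -0.49 ± 0.16 (adjusted p = 0.034). Ripk1 was unnamed here and Tnfrsf10b lay under the floor on too many arrays to be tested.

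Of 19 tested genes of the extrinsic death pathway, 2 rose, 2 fell and 15 were not called. The death receptor gene Fas was at 8.55 ± 0.34 (n = 7) in bone marrow-derived and 7.05 ± 0.26 (n = 2) in spleen cells (2.83-fold lower, adjusted p = 5.4e-04), and Mlkl, the executor of necroptosis, fell by 1.32 (adjusted p = 8.4e-04). Fasl, the ligand of Fas and a product of activated T and NK cells, rose by 2.50 ± 0.16, at least 3.82-fold, with no bone marrow-derived array above the floor. Tnfaip3, which encodes the NF-kB inhibitor A20, rose by 2.65 ± 0.47 (adjusted p = 0.0012). Of 5 BCL-2 family survival genes, Bcl2l1 (-1.57 ± 0.19), Bcl2a1a (-1.44 ± 0.24) and Bcl2l2 (-1.23 ± 0.29) were lower, Bcl2 was higher (1.56 ± 0.34), and Mcl1 was not called. Of 15 intrinsic pathway genes, the BH3-only genes Pmaip1 (1.17 ± 0.34) and Bmf (1.05 ± 0.34) were higher, Casp6 was lower (-1.40 ± 0.40), and 12 were not called. Adjusted over the list alone the counts in these 3 lists were the same, and no list passed its own test (adjusted p = 0.72, 0.47 and 0.41). Over the 3 lists together 5 genes were higher and 6 lower, and markers of T and NK cells were higher on the same spleen arrays, by medians of 2.46 and 3.25. The 5 higher genes became 2 without spleen replicate 1 and 1 without spleen replicate 2, in part because Fasl was then above the floor on 1 array only and not tested. Leaving out 1 spleen array, whichever it was, ended the calls of Pmaip1, Bmf, Casp6 and Bcl2l2, with adjusted p of 0.18, 0.13, 0.13 and 0.083 without replicate 1 and 0.073, 0.21, 0.11 and 0.051 without replicate 2. Their differences were 0.97, 1.14, -1.33 and -1.12 without replicate 1 and 1.37, 0.96, -1.48 and -1.33 without replicate 2, and with 1 spleen array the other group alone gives the spread. Against bone marrow replicates 5 to 7 alone Bmf was at 0.68 and Casp6 at -1.20, neither called. Pmaip1 was not called against replicates 1 to 4 alone (0.86). Nor was it called with the replicate block (0.51), which rests on replicates 1 and 2 of each group only. Without spleen replicate 2 Bcl2 was at 1.41 (adjusted p = 0.068), and without bone marrow replicate 2, 3 or 4 Bmf was at 1.04 (adjusted p = 0.055), 0.94 and 0.93 and not called. With the mean of all probe sets, Bcl2l1 was at -0.81, Bcl2l2 at -0.47, Bmf at 0.21 and Casp6 at -0.85, and none of them was called.

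**Figure D2:**
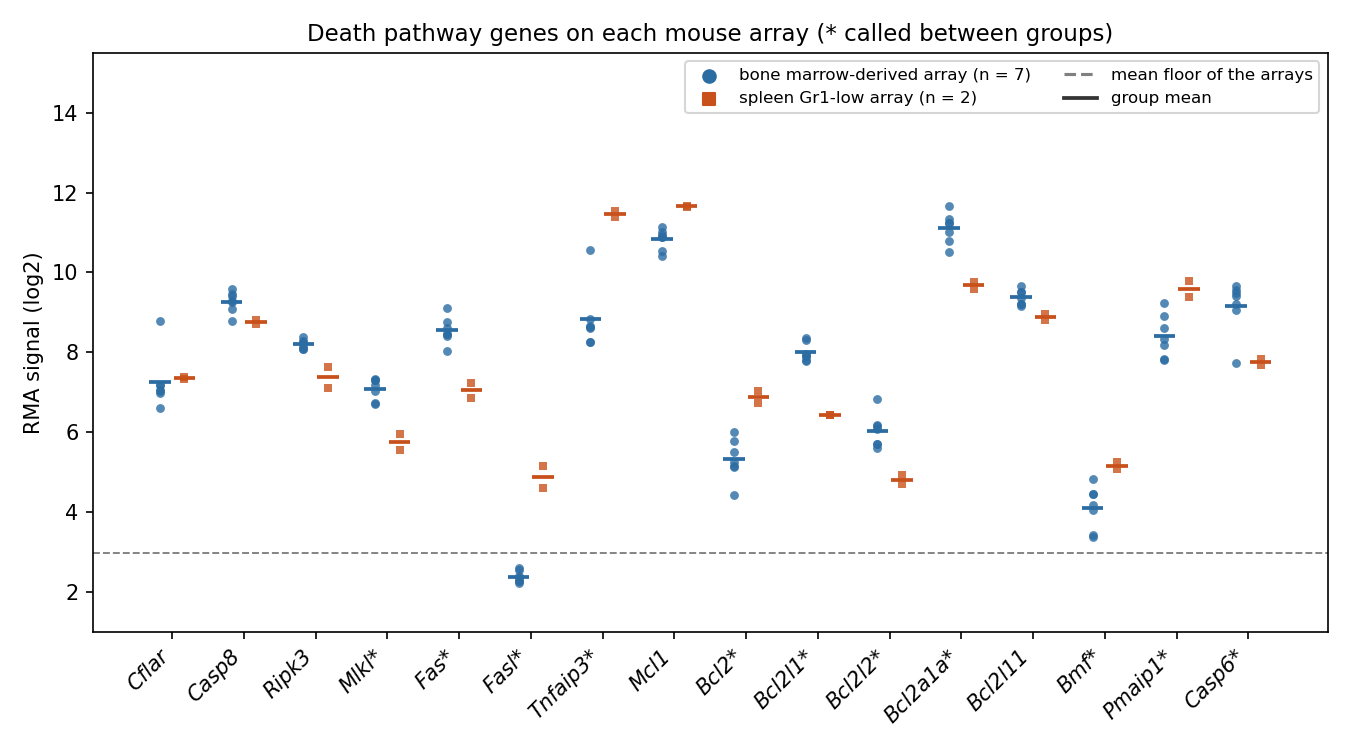
Log2 signal of 16 death pathway genes on each mouse array (circles, bone marrow-derived, n = 7; squares, spleen, n = 2), with bars at the group means and a dashed line at the mean floor of 2.96. Fasl lies under the floor in bone marrow-derived cells, Mcl1 lies at 10.84 in bone marrow-derived cells and 11.66 in spleen, and 1 bone marrow-derived array stands apart for Cflar at 8.78 and for Tnfaip3 at 10.56.

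Of 18 tissue macrophage markers, 15 rose in spleen, 0 fell and 3 were not called (camera adjusted p = 2.2e-11). They included Cd5l, the red pulp macrophage regulator gene Spic (5.56 ± 0.44), Vcam1 (3.05 ± 0.24) and the phosphatidylserine receptor gene Timd4 (2.56 ± 0.15, at least 3.12-fold). Of 13 monocyte markers, 8 rose and 1 fell, with Nr4a1 (5.37 ± 0.23), Ms4a4c (5.22 ± 0.42), Cx3cr1 (4.38 ± 0.29) and Klf4 (3.60 ± 0.48) in the lead, and with the mean of all probe sets Cx3cr1 was at 2.27. This list had an adjusted p of 1.1e-04, and an adjusted p = 0.18 with an estimated correlation. Of 11 dendritic cell markers, 7 rose and 0 fell, among them the growth factor receptor gene Flt3 (4.22 ± 0.22), Dpp4 (3.19 ± 0.44) and Irf8 (2.59 ± 0.38), and with the mean of all probe sets Dpp4 was at 1.79. Its adjusted p was 2.0e-06, and the adjusted p = 0.084 with an estimated correlation. Of 14 MHC class II presentation genes, 9 rose and 0 fell, or 10 and 0 adjusted over the list alone, with the transactivator gene Ciita (3.19 ± 0.46), H2-Eb2 (2.65 ± 0.21) and H2-Oa (2.37 ± 0.33), and with the mean of all probe sets Ciita was at 1.94. The adjusted p was 4.3e-06, and the adjusted p = 0.25 with an estimated correlation. B cells, whose markers rose on the same arrays by a median of 4.20, also express class II genes. Immediate early genes and T cell markers rose there as well, by medians of 1.92 and 2.46. Which cells, or what handling, gave the rises of the monocyte and dendritic cell markers was not tested.

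Members of the granulocyte lists went both ways. Of 17 neutrophil and granule genes, 7 fell, 3 rose and 7 were not called. Ms4a3 (-3.47 ± 0.21), cathepsin G (Ctsg, -2.54 ± 0.23), the collagenase gene Mmp8 (-1.98 ± 0.17) and proteinase 3 (Prtn3, -1.81 ± 0.23) were lower. The 3 that were higher, named after their values were seen, were the receptor genes Csf3r (2.22 ± 0.44) and Cxcr2 (1.61 ± 0.50) and the gelatinase gene Mmp9 (1.69 ± 0.56). The list's adjusted p was 0.017, and the adjusted p = 0.56 with an estimated correlation. It was 0.13 without spleen replicate 2 and 0.079 without bone marrow replicate 7. Of 7 eosinophil markers, 3 fell and 1 rose. Epx, Prg2 (-6.01 ± 0.18) and Prg3 (-5.56 ± 0.20, at least 43.8-fold lower), which encode granule proteins, were lower, and the eotaxin receptor gene Ccr3 was higher (3.44 ± 0.18, at least 7.94-fold). The list's adjusted p was 0.017, and the adjusted p = 0.40 with an estimated correlation. Of 9 mast cell and basophil markers, 4 fell and 1 rose, with Mcpt8 (-4.05 ± 0.24), Cpa3 (-3.56 ± 0.26), Ms4a2 (-2.78 ± 0.20, at least 6.68-fold lower) and Gata2 (-1.31 ± 0.20) lower. The list did not pass (adjusted p = 0.062), but passed in 7 of the alternatives, such as without spleen replicate 1 (adjusted p = 0.019), bone marrow replicate 6 (0.049) or bone marrow replicate 7 (0.046). Of 8 platelet and megakaryocyte markers, 4 fell and 1 rose, led by the platelet chemokine genes Pf4 (-5.20 ± 0.31) and Ppbp (-3.99 ± 0.31). Here the adjusted p was 0.0055, and the adjusted p = 0.43 with an estimated correlation. Of 8 endothelial and stromal markers, 2 fell, 0 rose and the list did not pass (adjusted p = 0.15).

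Markers of lymphocytes and erythroid cells were higher in spleen. All 10 B cell markers rose (adjusted p = 5.0e-13), with Blk at 4.92 ± 0.28, Fcer2a at 4.57 ± 0.19 (at least 18.8-fold) and Ighm at 3.21 ± 0.15 (at least 5.83-fold). Of 13 T cell markers 10 rose and 0 fell (adjusted p = 4.7e-11), among them the co-receptor genes Cd8b1 (4.80 ± 0.31, at least 21.4-fold) and Cd8a (3.59 ± 0.20) and the transcription factor gene Bcl11b (3.14 ± 0.19, at least 7.90-fold). Of 12 NK cell markers 10 rose and 0 fell (adjusted p = 8.7e-12), including granzyme A (Gzma, 5.91 ± 0.21, at least 45.5-fold), Il2rb (4.85 ± 0.21) and the chemokine gene Xcl1 (3.16 ± 0.16, at least 7.75-fold). With the mean of all probe sets Fcer2a was at 2.88 and Il2rb at 2.38. Of 11 erythroid markers 9 rose and 1 fell (adjusted p = 6.1e-11). Beside the hemoglobins, carbonic anhydrase 1 (Car1) rose by 7.28 ± 0.21 (at least 115-fold), Klf1 by 5.17 ± 0.21 and Rhag by 4.51 ± 0.14 (at least 15.1-fold). The probe set of Hba-a2, a close copy of Hba-a1 named after its value was seen, differed by -0.05. With an estimated correlation these 4 lists, the tissue macrophage list and the immediate early list stayed past the threshold, with adjusted p of 0.0099, 0.0099, 0.027, 0.011, 0.027 and 0.0099, and 16 lists passed with the preset correlation.

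Among pathway lists, immediate early genes rose. Of 16, 10 rose and 1 fell (adjusted p = 6.4e-09), with the AP-1 gene Fosb at 6.28 ± 0.31, the heat shock gene Hspa1b at 5.23 ± 0.41, Btg2 at 2.42 ± 0.19 and the phosphatase gene Dusp1 at 1.98 ± 0.19. Many of these genes respond to tissue dissociation within minutes, and spleen and culture differ in handling. Of 15 cholesterol synthesis genes, 11 fell and 0 rose (adjusted p = 2.9e-10, and adjusted p = 0.073 with an estimated correlation), with Fdps at -3.06 ± 0.26, squalene epoxidase (Sqle) at -2.66 ± 0.14, Stard4 at -2.42 ± 0.19 and Msmo1 at -2.32 ± 0.15 (-1.10 with the mean of all probe sets). Of 23 cell cycle genes, 9 fell and 0 rose, among them the mitotic genes Bub1 (-1.93 ± 0.31), Plk1 (-1.55 ± 0.21), Aurka (-1.41 ± 0.22) and Cdk1 (-1.31 ± 0.13). The adjusted p was 2.9e-05, and the adjusted p = 0.32 with an estimated correlation. Of 13 glycolysis genes only Tpi1, named after its value was seen, was called, and all 13 had negative differences with a median of -0.71 (adjusted p = 1.1e-04, and adjusted p = 0.073 with an estimated correlation). Of 17 oxidative phosphorylation genes, none was called with limma and 0 adjusted over the list alone (list adjusted p = 0.41). Of 8 housekeeping genes, 1 fell and 7 were not called (adjusted p = 0.17).

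Of 16 type I interferon response genes, 4 rose and 0 fell, or 3 and 0 adjusted over the list alone. The list's adjusted p was 0.015, and the adjusted p = 0.56 with an estimated correlation. The called genes were Ifit3 (2.05 ± 0.60), Oasl2 (1.99 ± 0.69), Oasl1 (1.57 ± 0.46) and Irf7 (1.48 ± 0.39), and none of the 4 stayed called when 1 spleen array, whichever it was, was left out (adjusted p from 0.088 to 0.21), though their differences stayed close, at 2.00, 1.93, 1.58 and 1.51 without replicate 1 and 2.10, 2.04, 1.56 and 1.45 without replicate 2. Without spleen replicate 1 the list had an adjusted p of 0.091. Against bone marrow replicates 5 to 7 alone its median was 0.24 (adjusted p = 0.064) and Irf7 was at 0.89, under the size threshold. Oasl2 also lost its call in alternatives that kept both spleen arrays. Among them were the mean of all probe sets (adjusted p = 0.055), centring on array medians (0.0525), and leaving out bone marrow replicate 2 (0.055) or 3 (0.063). Bone marrow-derived replicates 3 and 4 had list means, relative to the bone marrow-derived mean of each gene, of -0.92 and -1.09, against values from 0.09 to 0.66 on the other 5 arrays and 0.96 and 0.69 on the spleen arrays.

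Genes that act downstream of the culture cytokines split. Of 22 IL-6 and GM-CSF response genes, 5 rose, 8 fell and the list did not pass (adjusted p = 0.44), and 5 rose and 9 fell adjusted over the list alone. The STAT5 target Cish (-3.75 ± 0.28), the receptor subunit gene Csf2rb2 (-2.33 ± 0.18) and Il1rn (-2.37 ± 0.21) were lower, and Junb was higher (2.95 ± 0.23). Of 15 chemokine and receptor genes, 5 fell and 3 rose, or 6 and 3 adjusted over the list alone (list adjusted p = 0.17). The list median was -0.92, and -0.68 without spleen replicate 1. With the replicate block the median was -1.07 and the list passed (adjusted p = 0.0016). That fit rests on replicates 1 and 2 of each group only and does not speak for the other arrays. Ccl8 and Ccl12 (-3.63 ± 0.38, at least 8.03-fold lower) were lower, and Cxcl9 (4.12 ± 0.15, at least 13.2-fold) and its receptor gene Cxcr3 (3.16 ± 0.30) were higher. Of 21 suppressor effector genes, 3 rose, 3 fell and 15 were not called (list adjusted p = 0.14). Arginase 1 (Arg1), which depletes arginine, was lower by -2.63 ± 0.66 (adjusted p = 0.010), the ectonucleotidase gene Nt5e by -3.50 ± 0.33 and the PD-1 ligand gene Pdcd1lg2 by -2.67 ± 0.23, while Ptgs2 (2.04 ± 0.47) and Entpd1 (1.13 ± 0.26) were higher. Nos2, inducible nitric oxide synthase, was at 3.01 ± 0.21 (n = 7) and 3.05 ± 0.08 (n = 2), close to the floor (difference 0.04, adjusted p = 0.87). Without spleen replicate 1 Arg1 was at -2.09 (adjusted p = 0.14), Ptgs2 at 1.44 (0.13) and Entpd1 at 1.14 (0.051), and without replicate 2 Entpd1 was at 1.12 (0.060), with the spread from the other group alone. Against bone marrow replicates 5 to 7 alone Arg1 was at -2.22 (adjusted p = 0.12) and Ptgs2 at 1.96 (0.059), while the list passed (median -0.59, adjusted p = 0.029), as it did without the filter on dim genes (adjusted p = 0.039). With the mean of all probe sets Nt5e was at -1.73.

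Of 8 inflammasome and pyroptosis genes, 2 rose and 1 fell (list adjusted p = 0.28). The cytokine genes Il18 (3.17 ± 0.46) and Il1b (2.73 ± 0.70) were higher and the adaptor gene Pycard was lower (-1.10 ± 0.12). Without spleen replicate 1 Il1b was at 2.63 (adjusted p = 0.096) and Pycard stood at -0.94, under the size threshold, as it did at -0.66 with the mean of all probe sets, and without replicate 2 Il1b was at 2.83 (adjusted p = 0.083). Against bone marrow replicates 5 to 7 alone Il1b was at 1.96 (adjusted p = 0.085). Of 16 lysosome and cathepsin genes, 4 fell and 2 rose (list adjusted p = 0.22), with Gpnmb, the proton pump subunit gene Atp6v0d2 (-5.20 ± 0.35) and Ctsl (-1.91 ± 0.32) lower and Lgmn (1.43 ± 0.23) higher. With the mean of all probe sets Ctsl was at -0.99, under the size threshold. Of 17 endoplasmic reticulum stress genes, 3 rose and 2 fell (list adjusted p = 0.74), with Dnajb9 (1.17 ± 0.16) and Herpud1 (1.03 ± 0.16) higher and Trib3 (-1.82 ± 0.29) and Sdf2l1 (-1.20 ± 0.24) lower. Against bone marrow replicates 5 to 7 alone Sdf2l1 was at -0.94, under the size threshold. Dnajb9 stood at 0.96 without spleen replicate 1, and Herpud1 at 0.94 without replicate 2 and at 0.97 without bone marrow replicate 7. Except where stated, counts adjusted over the list alone equalled those over all genes.

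**Figure D3:**
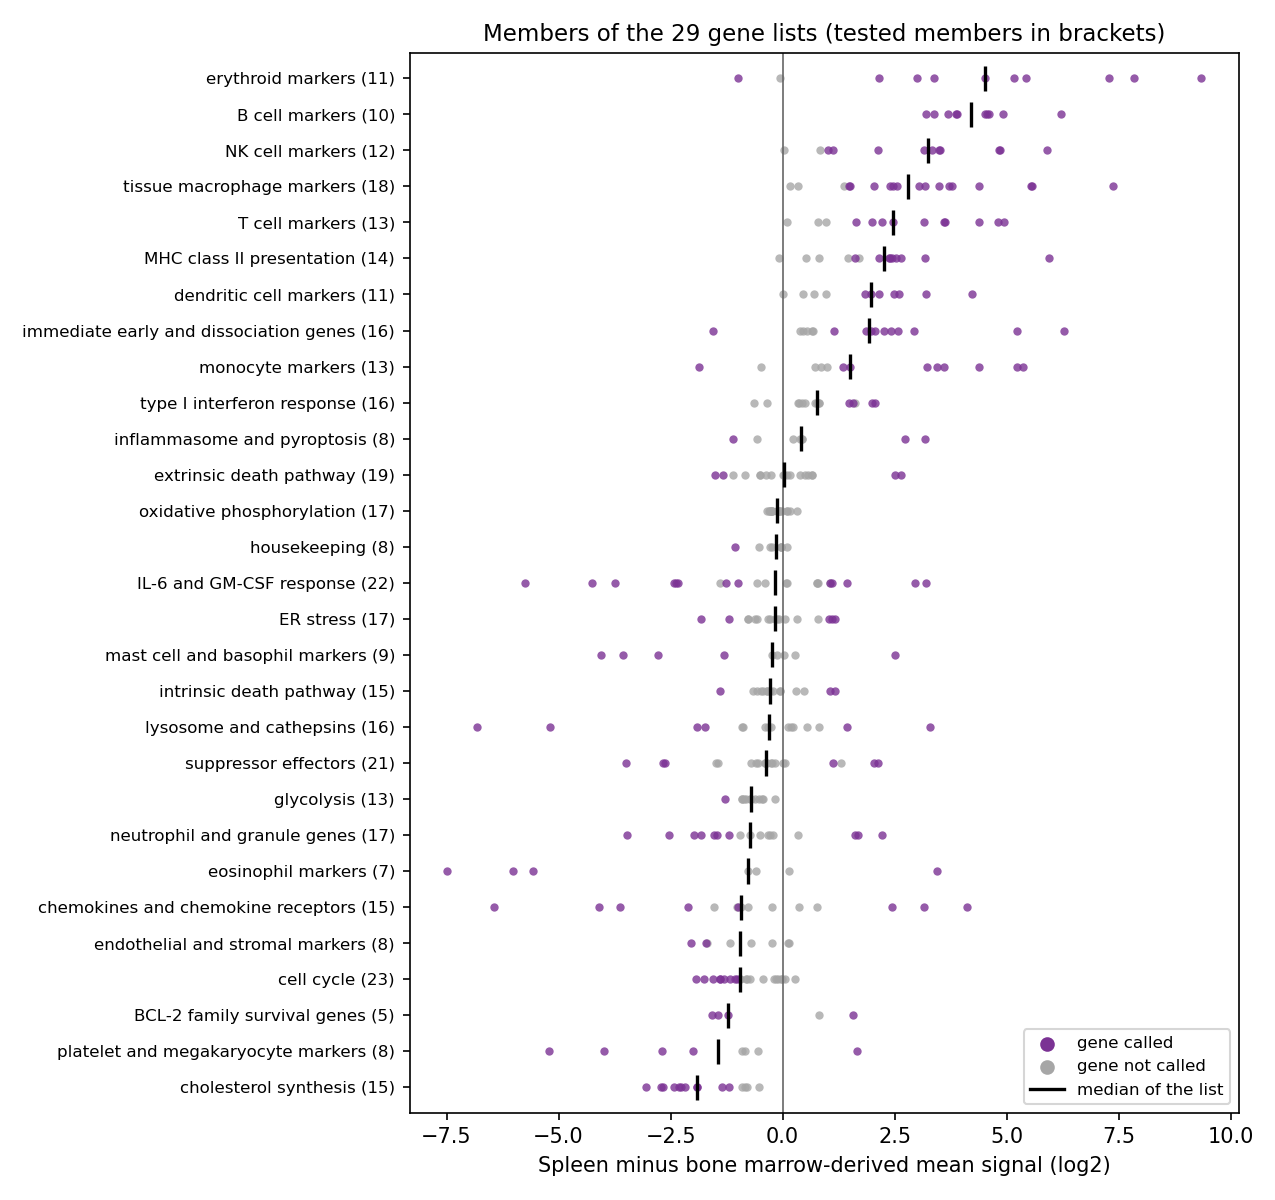
Log2 difference, spleen minus bone marrow-derived, of each tested member of the 29 lists (violet, called; grey, not called), with a black bar at the list median and the number tested in brackets. Erythroid and B cell markers have the highest medians, 4.51 and 4.20, and cholesterol synthesis genes the lowest, -1.92.

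The human arrays have no comparison group, and their values describe 1 population. Of 19750 named genes, 8473 (42.9%) lay above the floor on all 3 arrays. The monocyte receptor gene CD14, used for the sort, was at 11.07 ± 0.08 (SD, n = 3), ITGAM at 9.83 ± 0.06 and CSF1R at 6.89 ± 0.16, and 13 of 14 monocyte markers lay above the floor on all arrays. The calprotectin genes S100A8 (13.39 ± 0.08) and S100A9 (12.62 ± 0.12) and the oxidase gene CYBB (11.45 ± 0.09) were above the floor on all arrays as well. HLA-DRA was at 10.67 ± 0.16 and CD74 at 9.37 ± 0.46, in cells sorted for little surface HLA-DR, and 10 of 12 class II presentation genes lay above the floor. Above the floor on all arrays were also 1 of 12 B cell, 2 of 11 T cell, 5 of 13 NK cell, 4 of 20 neutrophil and 2 of 9 erythroid markers. ARG1 (2.30 ± 0.37), NOS2 (2.00 ± 0.22), IDO1 (3.18 ± 0.19) and CD274 (2.77 ± 0.33) were above the floor on none.

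Among human death pathway genes, MCL1 was at 11.98 ± 0.08 (n = 3) and CFLAR at 8.24 ± 0.25, both above the floor on every array. The same held for the TRAIL receptor gene TNFRSF10B (8.61 ± 0.07), BCL2A1 (8.86 ± 0.09), BCL2L11 (7.50 ± 0.35), CASP8 (7.39 ± 0.29), FAS (6.64 ± 0.28), RIPK3 (5.68 ± 0.30) and BCL2L1 (5.27 ± 0.39). BCL2 was at 3.00 ± 0.27 and above the floor on none. RIPK1 was unnamed here. Of the measured genes, 19 of 20 in the extrinsic list, 4 of 5 in the survival list and 10 of 16 in the intrinsic list lay above the human floor on all arrays. In mouse, on arrays normalized separately, 17 of 20, 5 of 5 and 15 of 15 lay above mouse floors on all bone marrow-derived arrays. On both spleen arrays 19, 5 and 15 did. Each mouse floor lay below the median of its array and the human floors lay above theirs, so these counts cannot be compared between the species.

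The last comparison asked which mouse cells had the expression order nearer to the human cells. Across 10381 genes with a shared symbol, which are not independent replicates, rho with the human mean was 0.613 ± 0.005 (SD, n = 7) for bone marrow-derived and 0.621 ± 0.011 (n = 2) for spleen arrays. The difference of 0.0084 was within the spread between arrays (exact two-sided permutation p = 0.19, where the smallest possible is 0.028). With Pearson's r on log2 values the difference was 0.012, at the smallest possible p of 0.028. With the genes chosen anew, the difference in rho was 0.021 without spleen replicate 2 and 0.0059 without replicate 1, with too few arrays left for a test. The spleen arrays stood at 0.629 and 0.614 and the bone marrow-derived arrays between 0.603 and 0.617.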

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

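The tests of the authors' normalization in the first pattern, of T and NK cell RNA in the second and of RNA quality in the third were chosen only after the result was seen. Of the 36 choices of 2 of the 9 mouse arrays, 1, the real one, called as many as its 1933 genes. The highest of the others called 4. Every other choice leaves at least 1 spleen array in the larger group, which widens the spread of that group. Few calls there were thus fixed in advance, and the comparison cannot exclude chance.

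Among 152 values tested for 1 of the 7 bone marrow-derived arrays standing apart, 17 did, where chance gives about 1 in 20, or 7.6. Of these, 15 belong to replicate 5. In log2 signal it was high for Cflar (8.78, others 6.61 to 7.17), Tnfaip3 (10.56, others 8.24 to 8.85), Il1b (12.42, others 8.81 to 10.32), Cx3cr1 (4.59), Spic (5.46, others at most 4.21) and Vcam1 (4.91). It was low for Casp6 (7.73, others from 9.05), Ctsg (10, others from 10.72), Prtn3 (10.78) and Ctsl (10.14). Its list means, relative to each gene's mean over the 7 bone marrow-derived arrays, were high for the extrinsic death pathway (0.47), suppressor effectors (0.66) and glycolysis (0.23). Its 18S ribosomal RNA control signal (9.19, others 10.04 to 10.57) and its rho with the human mean (0.603, others 0.612 to 0.617) were low. Replicate 7 was high for Hba-a1 (5.41, others at most 4.16) and low for Sdf2l1 (8.81).

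The first pattern weighed is the rise of B, T, NK and erythroid markers in spleen, of which 39 of 46 tested members were called higher. Of 36 further tested genes of these cells, 34, or 94.4%, were called higher, against 8.09% of all genes tested. They were listed after that rise but before their own values were seen. RNA of other cell types in the spleen fraction would give this. Genes of the same cell type rise together whatever their source, so the share does not tell CD11b+ lymphocytes from cells that escaped the selection. The spleen means of the brightest marker of each list, named after their values were seen, were 10.37 for Ms4a1, 8.91 for Cd3d, 8.45 for Gzma and 13.35 for Hba-a1, and of the 46 members 17 were above the floor on all bone marrow-derived arrays and 1 belonged to a second list. The authors' normalization would move genes of like level alike. As a set, 740 other genes with like bone marrow-derived levels showed no such shift, with a median difference of 0.124 (median absolute deviation 0.559). The 4 lists had 3.50 (1.98), but were weighed because they rose. RMA also removes a shift shared by most genes, so these values cannot decide on the normalization. Whether separate sources varied in share between the spleen arrays cannot be told apart from noise. List membership explained 2.89% of the variance of the difference between these arrays (permutation p = 0.742, 100000 permutations), and only 2 arrays exist. CD11b+ lymphocytes and changes within the myeloid cells of the spleen stay open, untested, and a sort gated against surface markers of B, T, NK and erythroid cells would remove the other cells.

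The second pattern is the difference in death pathway genes. A lower share of myeloid RNA in the spleen fraction would lower general myeloid genes together. The 12 such genes, on a list written before their values were seen, had a median of 0.0307 with a median absolute deviation of 0.45. The list as a whole thus did not drop. The 6 falls, with a median of -1.42, were chosen for falling, so their distance from the list is no test. Those myeloid genes did not move alike, with Aif1 at 3.51, Itgam at -1.80 and Cd33 at -1.25, so a lower share is not excluded. Whether Bcl2 and Fasl rose through RNA of T and NK cells cannot be told apart from a change in the myeloid cells, because only 2 spleen arrays exist; replicate 1 minus 2 was -0.54 for Fasl and -0.30 for Bcl2, beside -0.36 and -0.35 for the T and NK list means. The difference in tissue stays open as well, untested.

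The third pattern is a set of cytokine genes in bone marrow-derived replicate 5, chosen after their values were seen, with Csf3 at 9.71 (others 2.64 to 3.62), Il6 at 10.09 (others 4.20 to 6.46), Il1a at 9.98 (others 4.56 to 6.74) and Tnf at 10.08 (others 7.21 to 7.79). Stromal cells in that culture found no support in 11 stromal genes, which had a median difference of -0.15 (median absolute deviation 0.67). They ranged from -2.24 for Sparc to 1.42 for Col5a1, and 3 of them were highest in replicate 5. The 136 genes that stood apart upwards had a median of 1.74, but were chosen for being high. Some stromal genes lay near the floor, such as Col6a1, above it on 2 of the 7 arrays, so stromal cells are not excluded. RNA quality cannot be told apart, as its 3-prime minus 5-prime values of 0.74 for Actb and 0.65 for Gapdh were the highest of the 7, up to 0.24 outside the range of the others, and its 18S signal was the lowest. Of 16 other NF-kB target genes, on a list written before their values were seen, 15, or 93.8%, were highest in replicate 5. Chance would give 14.3% for independent genes and an array not picked for standing apart, and neither holds here. The share over all genes tested was not computed. These targets were thus high as a set in that culture, which does not decide the cause. A swap with a spleen array is argued against, as replicate 5 correlated with the other bone marrow-derived arrays at r from 0.978 to 0.984. With the spleen arrays r was 0.938 and 0.940. Other mislabelling stays open, and no group of the design gives a biological explanation to test. Without replicate 5 the comparison with spleen called 988 genes higher and 1009 lower.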

How the results depend on the processing

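Averaging bone marrow-derived replicates 1 with 2 and 3 with 4 was the only alternative chosen after the data were seen. This averaging called 908 genes higher and 896 lower. It ended the calls of Bmf (0.94, adjusted p = 0.065), Casp6 (-1.34, 0.051) and Oasl2 (1.77, 0.054). Across the alternatives 104 values of counts, likeness and human levels held. For gene counts and human levels this means only a count within a factor of 1.5 of the main one. For likeness it means the same side of the p threshold. A further 11 counts moved by over 1.5 times and 1 likeness value gained significance. Without a minimum size 1606 genes were higher and 2043 lower, with 8 and 10 death pathway genes; with a minimum of 2 log2 units these were 424, 227, 2 and 0, since fewer genes pass by construction. With the mean of all probe sets 3 death pathway genes were lower, and leaving out single arrays gave 1 to 5 that were higher, in part since Fasl was not tested without a spleen array; the cause of the other changes was not tested. Pearson's r raised the likeness difference to 0.012. Without single mouse arrays, 660 to 1011 genes were higher and 775 to 1021 lower. Replicate numbers 1 and 2 occur in both mouse groups but share only a number (the correlation across genes of replicate 1 minus 2 between the groups was -0.09). With the replicate block, arrays whose number occurs in 1 group only drop out of the difference, which then rests on replicates 1 and 2 of each group. The spread came from these few arrays alone, so the block is no check on the whole comparison. In this fit 1083 genes were higher and 1267 lower, and 5 named genes and the interferon list lost their calls. The IL-6 and GM-CSF response, chemokine and lysosome lists gained a call. For single named genes and lists, 3394 values kept their side, 108 lost it and 17 gained it, and no called value reversed. Only 2 spleen arrays and signals near the floor limit small differences and dim genes.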

Other observations

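The values in this part were looked up only after the result was seen, and no test was added. The bone marrow-derived arrays were not uniform. Replicates 1 and 2 correlated with r = 0.996 and replicates 3 and 4 with r = 0.995, the 2 closest pairs, though the labels name no shared culture. In 14 of 16 type I interferon response genes the lowest values of the group were those of replicates 3 and 4. Ifit1 was at 4.33 and 3.72 in these and between 6.68 and 7.93 in the other 5, and Xaf1 was at 6.61 and 6.45 against 8.05 to 8.99. Mx1 and Mx2 did not follow this order.

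With a range of at least 1 log2 unit, 222 genes set replicate 7 apart from the other 6 bone marrow-derived arrays (49 higher, 173 lower) and 208 set replicate 5 apart (136 higher, 72 lower), and at most 6 did so for any other array. In replicate 7 the lipid carrier gene Apoe was at 8.65 (others 4.15 to 6.09), the cyclin gene Ccnd2 at 7.97 (others 9.53 to 9.89) and the nucleolar genes Nolc1 at 6.16 (others 7.66 to 8.15) and Nop56 at 7.70 (others 8.80 to 9.47). In replicate 5 the itaconate synthesis gene Acod1 was at 11.88 (others 8.12 to 9.09), the gelatinase gene Mmp2 at 9.49 (others 5.20 to 5.94), and fibronectin (Fn1) was at 4.60 (others 7.44 to 9.20).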
